A study of Mus musculus with 8 samples.

How the data were processed

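The series holds 8 RNA-seq libraries of mouse colon, 4 from animals given water (Control) and 4 from animals given 3% DSS in the water for 7 days, as the labels give them. RNA was total RNA after removal of ribosomal RNA, and libraries were made with a kit for low input, per the labels' protocols. The values used are read counts per gene, deposited in 1 table for all libraries and named as counts per the file headers. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, HTSeq 0.9.1 and edgeR without a version, with the mm10 genome build, and do not give the role of each. The gene annotation and the strandedness used for counting are not given in the sources used here. The table's 8 other per-sample columns were not used here. Judged from the values, the table keeps protein-coding genes with at least 1 count in some library. Gene names are those of the table, and several differ from current ones, among them Chi3l3, Irg1, Emr1, Igj, Cyr61 and Ctgf.

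Groups followed the labels. Counts of the 17697 genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 14631 genes. Libraries were scaled with TMM factors, from 0.918 to 0.956 in Control and 1.05 to 1.10 in DSS, and DSS was compared with Control by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. CPM and log2 CPM (prior count 2) were computed from the counts and the scaling factors. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the lists. Principal components were computed from centred log2 CPM of the tested genes, and the groups were compared on the first component by exact permutation. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The random seed was 1.

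The 36 gene lists, the tests, the alternatives other than leaving out overlapping genes, and the rule for named genes were fixed before the data were examined. The rule named the 6 genes with the highest and the 6 with the lowest log2 difference among genes past the threshold whose DSS values all lay outside the Control range, with a mean of at least 5 CPM, leaving out unnamed gene models and rearranging receptor segments. It also named, for each list, the 2 changed members with the largest difference in the direction most of its changed members took and the 1 with the largest difference the other way, with a mean of at least 1 CPM. Some genes that the rule names are not reported here. All other genes in the text were chosen after their values were seen. Genes with 0 counts in a group were compared with a floor of 3 counts over the group, and genes with 1 to 3 counts were given a ratio of counts with a 95% counting interval, which covers counting error only.

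Gene positions came from GENCODE M21 (GRCm38, the same assembly as mm10) by gene ID. All 96 genes named by the rule and reported and 14548 of the tested genes (99.4%) were found there. Genes of families with near-identical members can exchange reads, among them the Saa, Hba and Hbb, Gsdmc, Ugt1a and Ugt2b, Cyp2c, Hsd3b, Reg3, Mcpt, Hist1 and Stfa genes, and 30 names are carried by more than 1 gene ID. Replicates are biological per the labels, so p-values of the gene tests measure the spread between these samples. Camera p-values with the preset correlation compare a list's genes with all other tested genes and are not a measure of that spread. Every pair of libraries within a group differed by a chi-square per gene of 15.7 to 195, so the libraries are distinct. Library totals ran from 21096703 to 32538072 counts, so a gene at 1 CPM rests on about 22.2 to 34.5 counts after scaling in a library. The spread within groups, as the median SD of log2 CPM, was 0.21 in Control and 0.28 in DSS.

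The gene test was tested on simulated counts drawn from the real means and library sizes for DSS against Control over 14491 genes. It recovered 60% of 100 genes changed 2-fold and 90.9% of 99 genes changed 4-fold. Of its calls 5.66% were false, and 0 had the wrong sign. The simulation changed 200 genes, against 62.7% of tested genes called in the real data. The adjusted threshold depends on the share of changed genes, so these rates do not describe the real comparison.

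The alternatives were DESeq2's size factors, library size only, upper quartile factors, no filter, a filter of at least 10 counts in at least 4 libraries, the Wald test of DESeq2 1.42.0, limma-voom with sample weights, the replicate number as a block, a threshold of 0.01, leaving out each library, and leaving out unnamed models. For lists they were an estimated inter-gene correlation, the fry rotation test and lists without shared genes, and for principal components the 500 most variable genes and a prior count of 0.5. Leaving out genes that share at least 20% of their exon bases with another gene was chosen after seeing the data. Tests on FPKM were not run because no FPKM values were used.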

Results

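Total RNA from the colon of mice that drank plain water (Control, 4 libraries) or water containing 3% DSS for 7 days (DSS, 4 libraries) was sequenced after removal of ribosomal RNA. DSS is dextran sulfate sodium, a polymer that damages the lining of the colon and is widely used to induce colitis in mice. Read counts were given for 17697 genes, all annotated as protein-coding. The library totals were 30588664, 30202846, 26439354 and 24546377 counts in Control replicates 1 to 4 and 21096703, 32538072, 29535001 and 29165062 counts in DSS replicates 1 to 4. Levels are CPM, counts per scaled library size, as mean ± SD (n = 4 libraries per group), and log2 differences are DSS minus Control ± SE. The comparison asked which transcripts of the colon differ between mice with DSS and mice with water alone.

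In the DSS group 18 of 20 tested neutrophil markers, 21 of 22 genes of matrix-degrading enzymes, 19 of 19 endothelial genes and 12 of 17 cytokines rose, and 1 cytokine fell. Of colonocyte markers 19 of 28 fell and 4 rose, of junction genes 19 of 21 fell and 1 rose, and of proliferation genes 24 of 28 fell and 0 rose. No list's call held with an estimated correlation (smallest camera adjusted p = 0.247). S100a8, a calcium-binding protein abundant in neutrophils, rose from 6.87 ± 2.47 to 879 ± 285 CPM and was chosen after its values were seen. Mmp3, a metalloproteinase that degrades extracellular matrix, rose from 9.27 ± 4.34 to 860.2 ± 463 CPM. Cldn2, which forms cation pores in tight junctions, fell from 233 ± 24.6 to 1.904 ± 0.166 CPM, Slc26a3, the chloride and bicarbonate exchanger of surface colonocytes, from 1475 ± 261 to 49.7 ± 33.1 CPM, and Cenpf, a kinetochore protein of dividing cells, from 60.9 ± 23.8 to 6.86 ± 3.05 CPM.

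Of 14631 genes tested with edgeR's quasi-likelihood test, 9170 (62.7%) changed at an adjusted p threshold of 0.05, 4740 of them higher and 4430 lower in DSS. At least 2-fold changes were found for 5726 genes (3377 higher, 2349 lower) and at least 4-fold changes for 2593 genes (1597 higher, 996 lower). With scaling by library size only, which moved the median log2 difference of all genes by 0.19, the number of genes higher in DSS was 5740 and of genes lower in DSS 3459. The share of calls that were higher was then 62.4% in place of 51.7%. The 4 DSS values lay outside the range of the 4 Control values for 8642 genes, 59.1% of those tested, where chance gives 2.86%. The first principal component held 82.0% of the variance and placed the Control libraries between -105 and -90.2 and the DSS libraries between 75.4 and 113 (exact permutation test, two-sided, p = 0.0286, the smallest value that this design can give). The second component held 5.62% of the variance, with scores of 25.9 and 16.3 in Control replicates 1 and 2, -19.3 and -27.0 in Control replicates 3 and 4, and -46.0 in DSS replicate 3 against 7.54 to 26.7 in the other DSS libraries. The 20 most abundant genes took 7.56% to 8.66% of the counts of each Control library and 5.85% to 6.55% of each DSS library. Counts were given for only 5 of the 13 mitochondrially encoded genes. These 5 took 0.584% to 0.748% of the counts of each Control library and 0.416% to 0.605% of each DSS library.

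**Figure D1:**
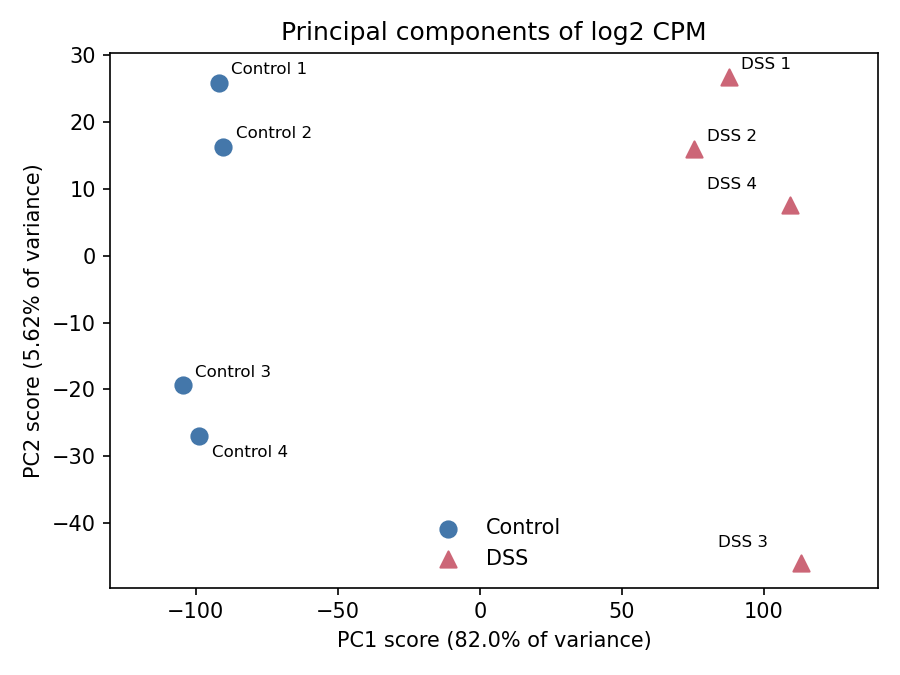
Scores of the 8 libraries on the first (horizontal) and second (vertical) principal components of log2 CPM over the tested genes, each point 1 library, circles for Control and triangles for DSS. The groups lie apart on the first component, from -105 to -90.2 against 75.4 to 113, and the second component, with 5.62% of the variance, separates Control replicates 1 and 2 from 3 and 4.

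The 6 genes with the highest log2 differences under the naming rule coded for cytokines, chemokines and products of myeloid or epithelial cells. Il19, a cytokine of the interleukin-10 family (ENSMUSG00000016524, chromosome 1, 130932656 to 130940115, minus strand, 6 exons in mm10), had 0 counts in all Control libraries. It was at 13.04 ± 14.5 CPM in DSS, at least 468-fold higher against a floor of 3 counts over the Control group. Without DSS replicate 4, at 33.8 CPM, it was at 6.12 ± 5.43 CPM and at least 222-fold higher. Prss22, a secreted serine protease (ENSMUSG00000045027, chromosome 17, 23993534 to 23998100, minus strand, 6 exons), had 2 counts over the Control libraries and 1381 over the DSS libraries, a ratio of 602 with a 95% counting interval of 166 to 4977, or 925 (166 to 36564) without Control replicate 3. Stfa2l1, a stefin of neutrophils (ENSMUSG00000059657, chromosome 16, 36156811 to 36161953, plus strand, 3 exons), had 3 counts against 1431, a ratio of 416 with an interval of 142 to 2019.5, or 974 (174 to 38486) without Control replicate 4. Near-identical stefin genes make its value uncertain. Cxcl3, a neutrophil-attracting chemokine (ENSMUSG00000029379, chromosome 5, 90786103 to 90789600, plus strand, 4 exons), rose 172-fold, from 0.270 ± 0.232 to 49.4 ± 36.0 CPM (log2 difference 7.43 ± 0.71, edgeR adjusted p = 2.02e-05), or 259-fold without Control replicate 1 and 111-fold without DSS replicate 4. Mmp8, the neutrophil collagenase (ENSMUSG00000005800, chromosome 9, 7558456 to 7568485, plus strand, 10 exons), rose 162-fold, from 1.17 ± 0.562 to 194 ± 71.1 CPM (log2 difference 7.34 ± 0.45, edgeR adjusted p = 1.52e-06). Marco, a scavenger receptor of macrophages (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024, minus strand, 17 exons), rose 149-fold, from 0.668 ± 0.397 to 103 ± 92.6 CPM (log2 difference 7.22 ± 0.79, edgeR adjusted p = 4.47e-05), or 84.1-fold without DSS replicate 4, at 238 CPM.

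The 6 genes with the lowest log2 differences included enzymes of glucuronidation and of the urea cycle. Ugt2b35, a UDP-glucuronosyltransferase (ENSMUSG00000035811, chromosome 5, 87000860 to 87013275, plus strand, 6 exons), fell from 23.8 ± 3.83 to 0.0867 ± 0.0421 CPM (log2 difference -8.08 ± 0.31, edgeR adjusted p = 1.16e-07). Otc, ornithine transcarbamylase (ENSMUSG00000031173, chromosome X, 10252305 to 10321024, plus strand, 10 exons), fell from 10.8 ± 0.802 to 0.0442 ± 0.0511 CPM (log2 difference -7.87 ± 0.52, edgeR adjusted p = 1.08e-06). Without DSS replicate 2 its ratio of Control to DSS was 466 (129 to 3850.2), from 2 counts in DSS. Cps1, the carbamoyl phosphate synthetase that precedes it in the urea cycle (ENSMUSG00000025991, chromosome 1, 67123026 to 67231259, plus strand, 38 exons), fell from 41.9 ± 12.5 to 0.206 ± 0.189 CPM (log2 difference -7.54 ± 0.52, edgeR adjusted p = 2.33e-06). S100g, the intestinal calcium-binding protein calbindin-D9k (ENSMUSG00000040808, chromosome X, 162961992 to 162964599, minus strand, 3 exons), fell from 100.3 ± 56.7 to 0.441 ± 0.218 CPM (log2 difference -7.76 ± 0.64, edgeR adjusted p = 8.15e-06). Cyp2f2, a cytochrome P450 (ENSMUSG00000052974, chromosome 7, 27119909 to 27133660, plus strand, 10 exons), fell from 23.6 ± 8.12 to 0.141 ± 0.145 CPM (log2 difference -7.41 ± 0.64, edgeR adjusted p = 9.75e-06), 170.2-fold or, without DSS replicate 2, 268-fold. Nox1, the NADPH oxidase of colonic epithelium (ENSMUSG00000031257, chromosome X, 134086421 to 134221956, minus strand, 13 exons), fell from 112 ± 46.1 to 0.737 ± 0.151 CPM (log2 difference -7.24 ± 0.34, edgeR adjusted p = 2.90e-07).

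The cytokine and chemokine lists ranked high in DSS. Of 17 tested inflammatory cytokines 12 rose, 1 fell and 4 did not pass, with a median log2 difference of 3.33, the same with Il22 at its bound (camera adjusted p = 6.49e-04, and adjusted p = 0.358 with an estimated correlation). Il22, a cytokine that acts on epithelium, had 0 Control counts and was at least 132-fold higher in DSS, at 3.82 ± 1.85 CPM. Il11, a cytokine of the interleukin-6 family, rose 69.4-fold, from 0.994 ± 0.360 to 69.6 ± 25.9 CPM. The member that fell was Il18, an interleukin-1 family cytokine made by epithelium, from 194 ± 21.7 to 28.8 ± 8.83 CPM. Among cytokines chosen after their values were seen, Il1b rose 66.6-fold and Il6 35.3-fold, while the log2 difference of Tnf was -0.04 ± 0.30 (edgeR adjusted p = 0.914), at 26.6 ± 12.8 to 25.8 ± 2.58 CPM. Of 25 tested chemokines 18 rose, 2 fell and 5 did not pass, with a median of 2.41 (camera adjusted p = 5.08e-04, and adjusted p = 0.358 with an estimated correlation). Of the chemokines 18 rose and 3 fell when adjusted over the list alone. Besides Cxcl3, Cxcl5, another chemokine for neutrophils, rose 92.2-fold, from 6.52 ± 1.01 to 602 ± 228 CPM. Ccl28, a chemokine made by mucosal epithelium, fell 21.3-fold, from 469.9 ± 66.0 to 22.1 ± 13.9 CPM. Relative to the Control mean, Control replicates 1 and 2 scored 0.58 and 0.34 for cytokines and 0.43 and 0.44 for chemokines, and replicates 3 and 4 scored -0.45 and -0.47, and -0.36 and -0.51. The antimicrobial and acute-phase list moved in both directions, with 12 of 20 tested members higher and 6 lower, a median of 2.14 and no call for the list (camera adjusted p = 0.213). Reg3b, an antibacterial lectin, rose 135-fold, from 0.207 ± 0.267 to 29.9 ± 15.3 CPM, or 348-fold without Control replicate 1, at 0.595 CPM. Saa3, an acute-phase apolipoprotein with close paralogs, rose from 14.1 ± 6.37 to 1872 ± 1053 CPM, and Nox1 fell as given above. Lcn2, an iron-scavenging protein chosen after its values were seen, rose 27.4-fold, from 25.6 ± 14.5 to 702 ± 384 CPM. The counts of the cytokine and antimicrobial lists were the same when adjusted over the list alone.

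Markers of myeloid cells and of T and NK cells were higher in DSS. Of 20 tested neutrophil markers 18 rose, 0 fell and 2 did not pass, with the highest median of all lists, 6.36 (camera adjusted p = 9.11e-09, and adjusted p = 0.358 with an estimated correlation). Besides Stfa2l1 and Mmp8, S100a9, the partner of S100a8 that was chosen after its values were seen, rose 123-fold, from 9.39 ± 3.38 to 1157 ± 407 CPM. Ly6g, a surface protein used to identify neutrophils and likewise chosen afterwards, was at 146 ± 30.7 to 203 ± 96.3 CPM (log2 difference 0.48 ± 0.31, edgeR adjusted p = 0.209). Without DSS replicate 3 its edgeR adjusted p was 0.0420 and without DSS replicate 2 it was 0.682, the lowest and highest over the alternatives. Of 23 tested monocyte and macrophage markers 20 rose, 0 fell and 3 did not pass, with a median of 2.22 (camera adjusted p = 1.48e-06, and adjusted p = 0.358 with an estimated correlation). Chi3l3, a chitinase-like protein of macrophages now named Chil3, rose 131-fold, from 5.59 ± 2.83 to 739 ± 427 CPM. It was at 1378 CPM in DSS replicate 4 against 505 to 557 CPM in the other DSS libraries. Arg1, an arginase of macrophages, rose 62.3-fold, from 0.664 ± 0.457 to 42.4 ± 46.4 CPM, or 28.8-fold without DSS replicate 4, at 111 CPM. Of 19 tested T and NK cell markers 16 rose, 0 fell and 3 did not pass, with a median of 1.81 (camera adjusted p = 1.39e-04, and adjusted p = 0.358 with an estimated correlation). Foxp3, the transcription factor of regulatory T cells, rose 15.3-fold, from 0.625 ± 0.197 to 9.70 ± 2.32 CPM, although 31.5% of its exon bases are shared with another gene on either strand. Il2ra, the interleukin-2 receptor alpha chain, rose 11.7-fold, from 2.51 ± 1.498 to 29.7 ± 8.54 CPM. Control replicates 1 and 2 scored 0.35 and 0.46 for neutrophil markers and 0.21 and 0.43 for T and NK cell markers, against -0.45 and -0.36, and -0.25 and -0.40, in replicates 3 and 4. These 3 lists had the same counts when adjusted over the list alone.

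B and plasma cell markers had a median of 1.44 and 5 of 17 tested members rose, 0 fell and 12 did not pass (camera adjusted p = 0.0104, and adjusted p = 0.413 with an estimated correlation). Adjusted over the list alone, 5 also rose. Over all 14631 tested genes 4740 rose, so 5 of 17 does not exceed the share over all genes. Without Control replicate 2 the number of members of this list that rose was 10. Derl3, an endoplasmic reticulum protein abundant in plasma cells, rose 6.48-fold, from 2.14 ± 0.221 to 13.9 ± 3.51 CPM. Pou2af1, a transcriptional coactivator of B cells, rose 4.19-fold, from 27.4 ± 13.01 to 115 ± 45.2 CPM. The mean log2 level of the list relative to the Control mean was 1.15 and 1.37 in Control replicates 1 and 2, -1.31 and -1.21 in Control replicates 3 and 4, and 1.29 to 2.36 in the DSS libraries. Of 12 tested mast cell and eosinophil markers 8 rose, 1 fell and 3 did not pass, and adjusted over the list alone 8 rose and 2 fell. The median was 1.51 and the list was not called (camera adjusted p = 0.107). With 1 library left out that value ran from 0.0448, without Control replicate 3, to 0.122, and 2 members fell without DSS replicate 2 or 3. Il5ra, the interleukin-5 receptor of eosinophils, rose from 0.0525 ± 0.105 to 5.22 ± 2.35 CPM, and was at least 131-fold higher without Control replicate 1, the only Control library with counts. Prg2, the eosinophil major basic protein, rose 6.81-fold, and Alox15, a lipoxygenase, fell 3.56-fold.

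Most tested markers of goblet cells and colonocytes and most junction genes fell in DSS. Of 20 tested goblet cell markers 0 rose, 16 fell and 4 did not pass, with a median of -1.80 (camera adjusted p = 1.32e-04, and adjusted p = 0.413 with an estimated correlation). Klk1, a kallikrein, fell 13.4-fold, from 628 ± 102 to 46.7 ± 31.8 CPM. Creb3l4, a membrane-bound transcription factor, fell 8.45-fold, from 25.9 ± 2.81 to 3.06 ± 1.03 CPM. Muc2, the main secreted mucin of the colon and chosen after its values were seen, was at 1538 ± 254 to 1246 ± 815 CPM (log2 difference -0.30 ± 0.46, edgeR adjusted p = 0.588). Its value is uncertain because 2 other identifiers carry the same name. Of 28 tested absorptive colonocyte markers 4 rose, 19 fell and 5 did not pass, with a median of -1.59 (camera adjusted p = 0.00266, and adjusted p = 0.486 with an estimated correlation). Besides Slc26a3, Cyp2c55, a cytochrome P450, fell 109-fold, from 459 ± 185 to 4.25 ± 2.35 CPM. Sgk1, a kinase that regulates sodium channels, rose 4.83-fold, from 64.4 ± 2.75 to 311 ± 112 CPM. Of 21 tested genes of tight and adherens junctions 1 rose, 19 fell and 1 did not pass, with a median of -2.17 (camera adjusted p = 3.01e-06, and adjusted p = 0.358 with an estimated correlation). Besides Cldn2, the claudin Cldn8 fell 11.7-fold, from 331 ± 60.7 to 28.2 ± 18.998 CPM. Cldn1 rose 5.09-fold, from 6.17 ± 1.40 to 31.5 ± 22.3 CPM, or 3.32-fold without DSS replicate 2, and 2 junction genes rose without Control replicate 4 or DSS replicate 3. Epcam, a surface protein of epithelial cells in general and chosen after its values were seen, fell 5.56-fold, from 2285 ± 246 to 411 ± 247 CPM. In a list of general epithelial genes drawn up after the data were seen, 13 of 14 tested members fell, with a median of -2.77 and a range of -3.96 to -1.19. For the goblet cell, colonocyte and junction lists the counts adjusted over the list alone were the same.

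The lists of rare epithelial cell types were not called. Of 15 tested enteroendocrine markers 8 rose, 2 fell and 5 did not pass, with a median of 1.16 (camera adjusted p = 0.0597). Its camera adjusted p was 0.0371 without Control replicate 3, 0.0418 without DSS replicate 2 and 0.0101 without DSS replicate 3, and at most 0.134 with another library left out. The hormone genes Nts and Sst rose 14.7-fold (from 0.160 ± 0.268 to 2.50 ± 1.18 CPM) and 9.03-fold (from 2.55 ± 0.446 to 23.0 ± 10.8 CPM). Without Control replicate 1 Nts had 2 Control counts and a ratio of 96.7 (26.5 to 802). Pyy, a hormone gene chosen after its values were seen, rose 2.24-fold. Pax6, a transcription factor of enteroendocrine cells, fell 2.88-fold (edgeR adjusted p = 0.0263). Its adjusted p was 0.0528, 0.0593 and 0.0507 without Control replicate 1, Control replicate 4 and DSS replicate 2, and leaving out any of these libraries left 1 member lower. Of 14 tested tuft cell markers 7 rose, 1 fell and 6 did not pass, with a median of 0.45 (camera adjusted p = 0.126). Alox5ap, which serves leukotriene synthesis and is also expressed by leukocytes, rose 15.2-fold. Chat, the acetylcholine-synthesising enzyme that the enteric neuron list also holds, rose 8.32-fold, or 13.7-fold without Control replicate 4, while Trpm5, the cation channel of tuft cells, fell 3.88-fold. Both lists had the same counts when adjusted over the list alone.

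Most tested nuclear genes of fuel use and detoxification fell, beside general epithelial genes with a median of -2.77. Of 24 tested genes of fatty acid oxidation and ketogenesis 0 rose, 21 fell and 3 did not pass, with a median of -1.09 (camera adjusted p = 4.13e-07, and adjusted p = 0.358 with an estimated correlation). Acss2, an acetyl-CoA synthetase, fell 12.2-fold, from 186 ± 19.5 to 15.2 ± 3.03 CPM. Hadh, a dehydrogenase of fatty acid oxidation, fell 6.80-fold, from 276 ± 40.1 to 40.5 ± 10.1 CPM. Of 30 tested nuclear genes of oxidative phosphorylation 1 rose, 26 fell and 3 did not pass, with a median of -1.27 (camera adjusted p = 9.11e-09, and adjusted p = 0.358 with an estimated correlation). Uqcrc2, a core subunit of respiratory complex III, fell 3.24-fold, from 454 ± 18.0 to 140.03 ± 13.99 CPM. Atp5o, a subunit of ATP synthase with 47.9% of its exon bases shared with another gene, fell 3.42-fold, from 224 ± 12.0 to 65.6 ± 4.51 CPM. Of 29 tested genes of drug and bile acid handling 2 rose, 24 fell and 3 did not pass, with a median of -3.02 (camera adjusted p = 4.13e-07, and adjusted p = 0.358 with an estimated correlation). Besides Cyp2c55, the glutathione transferase Gstm3 fell 76.9-fold, from 30.5 ± 5.83 to 0.381 ± 0.178 CPM. Cyp1b1, a cytochrome P450, rose 16.9-fold, from 0.156 ± 0.0829 to 2.77 ± 1.25 CPM. The table held 5 of the 13 mitochondrially encoded genes, of which 0 rose, 2 fell and 3 did not pass, mt-Nd5 with a log2 difference of -0.82 and mt-Nd4 of -0.61. For this list the median (0.75) and mean (0.34) were positive while the test ranked it low (camera adjusted p = 0.582). The median was 0.24 without DSS replicate 3, 0.47 without Control replicate 3 and 0.48 without Control replicate 4, and 1 member rose without DSS replicate 2. The mitochondrial scores were 0.70 and 0.39 in Control replicates 1 and 2 and -0.59 and -0.50 in replicates 3 and 4. Counts of these 4 lists adjusted over the list alone were the same.

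Most tested stem cell and cell division genes fell with the general epithelial genes (median -2.77), and part of the wound-associated list rose. Of 17 tested stem and progenitor markers 3 rose, 10 fell and 4 did not pass, with a median of -1.51 (camera adjusted p = 0.00716, and adjusted p = 0.247 with an estimated correlation). Lgr5, the receptor that marks crypt base stem cells, fell 42.7-fold, from 21.8 ± 2.79 to 0.521 ± 0.318 CPM. Ascl2, a transcription factor of these cells, fell 16.8-fold, from 2.94 ± 0.234 to 0.177 ± 0.109 CPM. Cd44, an adhesion receptor that leukocytes and stroma also express, rose 3.63-fold, from 125 ± 23.1 to 453 ± 100.1 CPM. Of 28 tested proliferation genes 0 rose, 24 fell and 4 did not pass, with a median of -2.26 (camera adjusted p = 2.09e-08, and adjusted p = 0.358 with an estimated correlation). Adjusted over the list alone, 25 fell. Besides Cenpf, the mitotic checkpoint kinase Bub1 fell 6.22-fold, from 34.2 ± 8.90 to 5.52 ± 1.75 CPM. Mki67, chosen after its values were seen, fell 5.05-fold, from 410.0 ± 109 to 81.2 ± 27.7 CPM. Of 7 tested replication-dependent histone genes 0 rose, 5 fell and 2 did not pass, with a median of -1.27 (camera adjusted p = 0.0482, and adjusted p = 0.413 with an estimated correlation). The list was not called without Control replicate 3 (adjusted p = 0.0579) or Control replicate 4 (adjusted p = 0.0581), with DESeq2's size factors (adjusted p = 0.0519) or with overlapping genes left out (adjusted p = 0.0818). The linker histones Hist1h1d and Hist1h1e fell 13.8-fold and 7.80-fold, the latter with 25.7% of its exon bases shared with another gene. Of 25 tested repair epithelium genes 14 rose, 4 fell and 7 did not pass, and adjusted over the list alone 15 rose. The median was 0.77 and the list was not called (camera adjusted p = 0.0601, from 0.0232 without DSS replicate 3 to 0.0933 without DSS replicate 2). It was called with the replicate number as a block (camera adjusted p = 0.0382) and with no filter on low counts (camera adjusted p = 0.0414). Ereg and Epgn, ligands of the epidermal growth factor receptor, rose 57.2-fold (from 21.4 ± 1.31 to 1227 ± 374 CPM) and 29.7-fold. The keratin Krt7 fell 3.57-fold. Control replicates 1 and 2 scored 0.45 and 0.02 for proliferation and -0.29 and -0.54 for histones, and replicates 3 and 4 scored -0.25 and -0.22, and 0.56 and 0.27. The stem cell and histone counts adjusted over the list alone were the same.

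Stromal, vascular and neural lists were higher in DSS, and smooth muscle markers were not called. Of 22 tested genes of metalloproteinases and the plasminogen system 21 rose, 0 fell and 1 did not pass, with a median of 3.75 (camera adjusted p = 1.10e-08, and adjusted p = 0.247 with an estimated correlation), and 1 member fell without DSS replicate 2. Besides Mmp3, the stromelysin Mmp10 rose 79.4-fold, from 7.11 ± 2.41 to 565 ± 345 CPM. Of 28 tested collagens and fibroblast markers 25 rose, 0 fell and 3 did not pass, with a median of 1.503 (camera adjusted p = 4.13e-07, and adjusted p = 0.358 with an estimated correlation). Col18a1, a basement membrane collagen, rose 16.9-fold, from 58.0 ± 6.45 to 978 ± 159 CPM. Lox, which cross-links collagen, rose 12.3-fold, from 27.9 ± 6.53 to 344 ± 191 CPM. The collagen and fibroblast scores were -0.24 and -0.16 in Control replicates 1 and 2 and 0.05 and 0.34 in replicates 3 and 4. All 19 tested endothelial and adhesion genes rose, with a median of 2.40 (camera adjusted p = 1.91e-08, and adjusted p = 0.247 with an estimated correlation). Sele and Selp, selectins that bind leukocytes to activated endothelium, rose 76.1-fold (from 0.136 ± 0.0718 to 10.5 ± 2.32 CPM) and 56.3-fold (from 3.20 ± 1.21 to 181 ± 68.1 CPM). Of 22 tested enteric neuron and glia markers 20 rose, 0 fell and 2 did not pass, with a median of 2.50 (camera adjusted p = 4.46e-07, and adjusted p = 0.358 with an estimated correlation). Gfap, a filament protein of glia, rose 20.2-fold, from 2.43 ± 0.361 to 48.9 ± 15.1 CPM. Phox2a, a transcription factor of autonomic neurons, rose 10.8-fold, from 0.298 ± 0.338 to 3.21 ± 1.80 CPM, or 19.6-fold without Control replicate 4. Of 19 tested smooth muscle markers 3 rose, 7 fell and 9 did not pass, with a median of -0.58 (camera adjusted p = 0.184), or -0.98 without DSS replicate 2 and -0.38 without DSS replicate 4. Casq2, a calcium store protein of muscle, and Hhip, a hedgehog-binding protein, fell 4.74-fold and 4.67-fold, and Cald1, an actin-binding protein, rose 2.36-fold. The counts of these 5 lists adjusted over the list alone were the same.

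**Figure D2:**
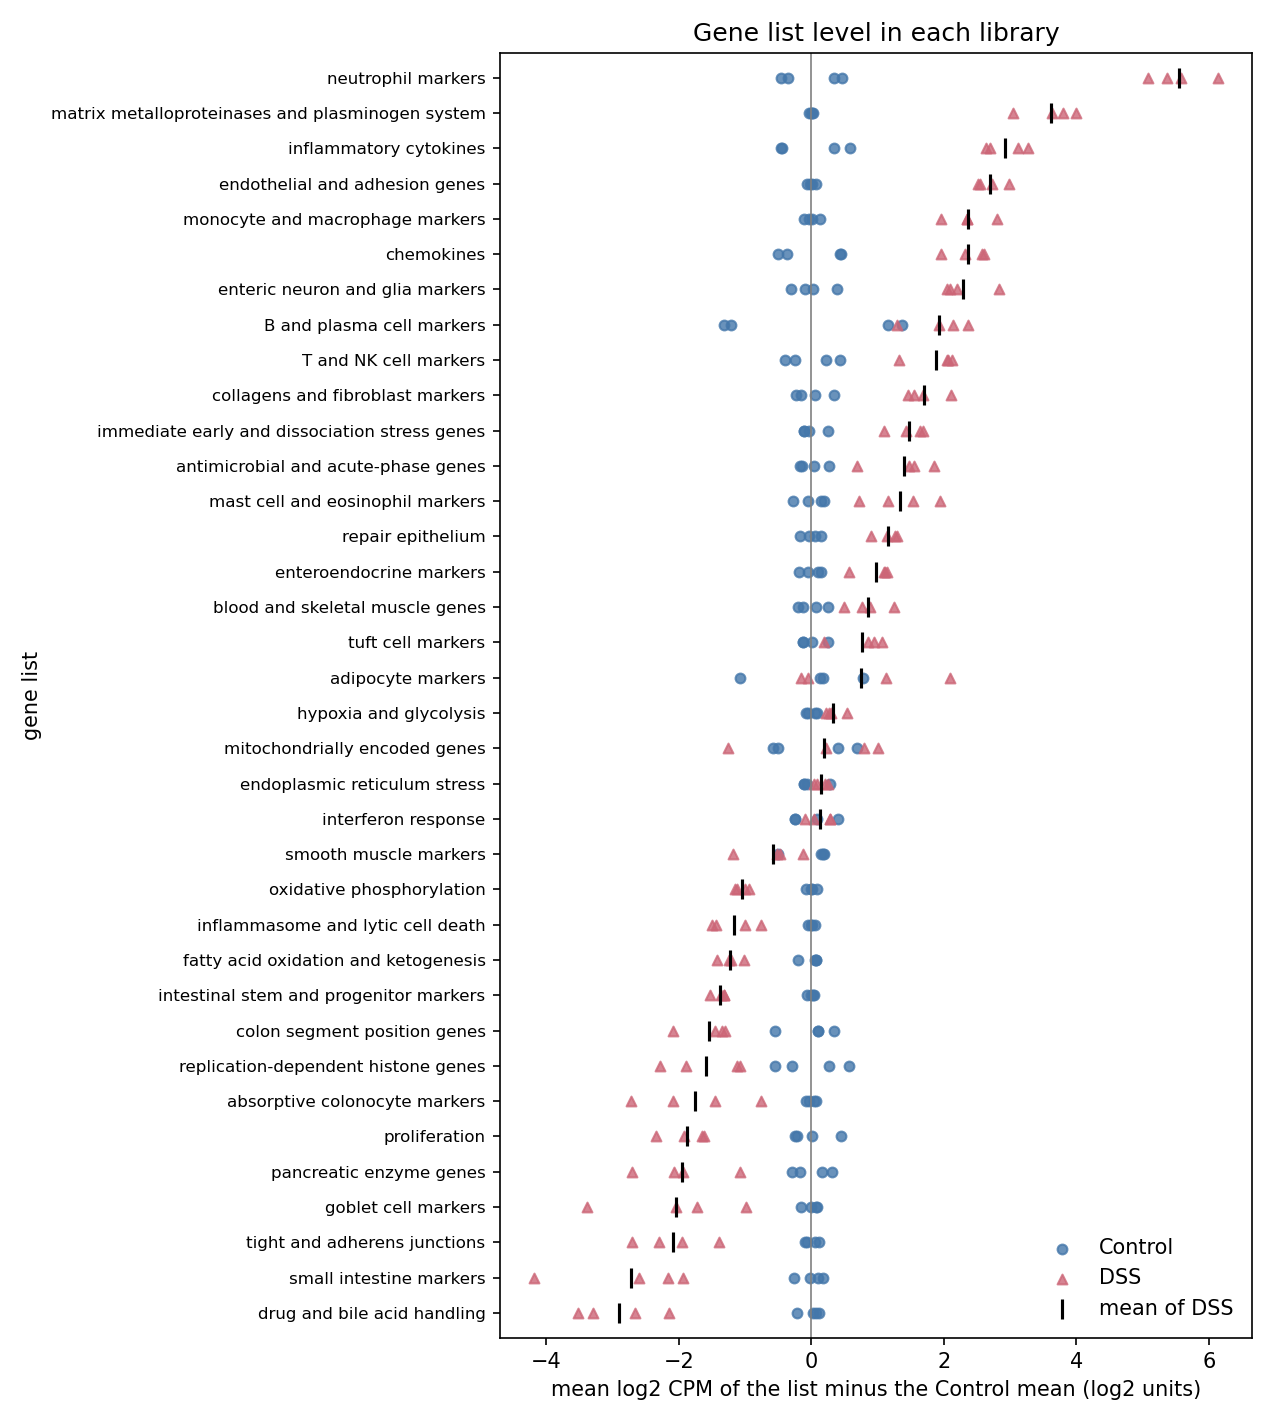
Level of each of 36 gene lists in each of the 8 libraries, as the mean log2 CPM of its tested members minus the Control mean (horizontal axis, log2 units), circles for Control, triangles for DSS and a bar for the DSS mean. Neutrophil markers lie highest in DSS, and the Control libraries of the B and plasma cell list form pairs at 1.15 and 1.37 and at -1.31 and -1.21.

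The lists of cell stress and innate sensing went several ways. Of 23 tested inflammasome and lytic cell death genes 5 rose, 14 fell and 4 did not pass, with a median of -1.25 (camera adjusted p = 0.0139, and adjusted p = 0.413 with an estimated correlation). Nlrp6, an inflammasome sensor of intestinal epithelium, fell 73.4-fold, from 311 ± 13.04 to 4.27 ± 1.69 CPM. Gsdmc4, a gasdermin with close paralogs, fell 30.3-fold, from 1997 ± 269 to 66.0 ± 43.0 CPM. Mefv, which codes for pyrin of myeloid cells, rose 15.6-fold, from 3.96 ± 1.61 to 62.4 ± 14.1 CPM. Of 21 tested immediate early and dissociation stress genes 13 rose, 0 fell and 8 did not pass, with a median of 0.80 (camera adjusted p = 0.00271, and adjusted p = 0.358 with an estimated correlation). Of this list 1 member fell without Control replicate 1 or without DSS replicate 2. Nr4a1, a nuclear receptor, rose 20.9-fold, and Dusp1, a phosphatase of MAP kinases, rose 15.4-fold, from 27.4 ± 3.51 to 421 ± 119.8 CPM. Of 33 tested interferon response genes 10 rose, 5 fell and 18 did not pass, with a median of 0.10 and no call (camera adjusted p = 0.725). Over all 14631 tested genes 4740 rose and 4430 fell, so neither count of this list exceeds the share over all genes. Adjusted over the list alone, 9 rose. Without Control replicate 2 the number that rose was 6, and 3 fell without Control replicate 1, Control replicate 3 or DSS replicate 4. With 1 library left out its median ran from -0.01, without Control replicate 4, to 0.27, without Control replicate 1. The interferon-inducible GTPases Iigp1 and Gbp4 rose 3.49-fold and 2.37-fold, and Oas1a, an antiviral synthetase, fell 2.60-fold. Iigp1 was at 207 CPM in Control replicate 1 against 62.5 to 63.6 CPM in the other Control libraries, and rose 5.35-fold without it. Of 27 tested hypoxia and glycolysis genes 10 rose, 6 fell and 11 did not pass, and the list was not called (camera adjusted p = 0.582). Its median was -0.03, its mean was 0.36 and the test ranked it high. With 1 library left out the median ran from -0.08, without Control replicate 3, to 0.04, without DSS replicate 3. Pfkfb3, a regulator of glycolysis, and Adm, the peptide adrenomedullin, rose 12.8-fold and 5.57-fold, and Car9, a carbonic anhydrase, fell 3.11-fold. Of 25 tested endoplasmic reticulum stress genes 6 rose, 5 fell and 14 did not pass, and the list was not called (camera adjusted p = 0.832). Adjusted over the list alone, 3 fell, as they did without Control replicate 1 or DSS replicate 1, 3 or 4. The median was -0.04, the mean was 0.14 and the test ranked the list high. With 1 library left out the median ran from -0.21, without Control replicate 2, to 0.04, without DSS replicate 3, and was also positive without Control replicate 1 (0.02). Chac1, a glutathione-degrading enzyme, and Ppp1r15a, a phosphatase subunit, rose 6.76-fold and 2.44-fold, and Pdia3, a protein disulfide isomerase, fell 1.87-fold. The medians of the interferon, hypoxia and endoplasmic reticulum stress lists over all 8 libraries lie nearer 0 than the shift of 0.19 between scalings, while 2 of the medians given above with 1 library left out (0.27 and -0.21) lie farther. Counts of the inflammasome, immediate early and hypoxia lists adjusted over the list alone were the same.

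Genes that mark position along the gut and neighbouring tissues were tested as checks on sampling. Of 12 tested colon segment position genes 2 rose, 9 fell and 1 did not pass, with a median of -1.76 (camera adjusted p = 0.00969, and adjusted p = 0.378 with an estimated correlation). Hoxb13, a homeobox gene of the distal gut, fell 18.1-fold, from 268 ± 48.1 to 14.8 ± 8.99 CPM. Hoxb8, a homeobox gene of another group, rose 6.20-fold, from 0.299 ± 0.411 to 1.82 ± 0.775 CPM, or 17.6-fold without Control replicate 4. In a set chosen after the data were seen, all tested Hox genes, groups 1 to 8 had 9 of 17 genes higher and 4 lower with a median of 1.15. Groups 9 to 13 had 1 of 11 higher (Hoxa11, 4.54-fold, with 34.98% of its exon bases shared with a gene on the other strand) and 10 lower with a median of -1.74. Of 6 tested small intestine markers 0 rose, 4 fell and 2 did not pass, with a median of -2.75 (camera adjusted p = 0.0229, and adjusted p = 0.358 with an estimated correlation). With 9 members tested in place of 6, this list was not called without Control replicate 1 (adjusted p = 0.310, 2 members higher, median -1.40), Control replicate 2 (adjusted p = 0.247, median -1.20) or Control replicate 3 (adjusted p = 0.257, 1 higher, median -1.46). It was also not called, again over 9 members, without Control replicate 4 (adjusted p = 0.210, median -1.56) or DSS replicate 3 (adjusted p = 0.472, 3 higher, median -1.01). With no filter on low counts its adjusted p was 0.271. Fabp6, the ileal bile acid-binding protein, and Rbp2, a retinol-binding protein, fell 46.6-fold and 7.03-fold. Without DSS replicate 1 Fabp6 had 2 DSS counts and a ratio of Control to DSS of 216 (59.4 to 1788). Of 11 tested adipocyte markers 5 rose, 1 fell and 5 did not pass, with a median of 1.37, or 0.29 without DSS replicate 2, and no call (camera adjusted p = 0.277). Fabp4, a fatty acid-binding protein of fat and vessels, rose 5.999-fold, and Cidec, a lipid droplet protein, rose 11.6-fold, or 6.95-fold without DSS replicate 2. The Cidec values of DSS and Control overlapped, and its edgeR adjusted p was 0.0101, or 0.0518 with the replicate number as a block. Pck1, an enzyme of gluconeogenesis that colonocytes also express, fell 23.8-fold. Of 11 tested blood and skeletal muscle genes 6 rose, 4 fell and 1 did not pass, with a median of 1.996 and no call (camera adjusted p = 0.247). The red cell genes Hbb-bt and Alas2 rose 21.1-fold and 13.8-fold, and the skeletal muscle myosin Myh2 fell 27.1-fold. Without DSS replicate 2 Myh2 had 2 DSS counts and a ratio of Control to DSS of 97.2 (26.6 to 807). Of 2 tested pancreatic enzyme genes Cela1 fell 26.3-fold, from 222 ± 53.8 to 8.43 ± 3.52 CPM, and 1 did not pass (camera adjusted p = 0.404), with 1 member higher without DSS replicate 4. For these 5 lists nothing changed in the counts adjusted over the list alone.

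**Figure D3:**
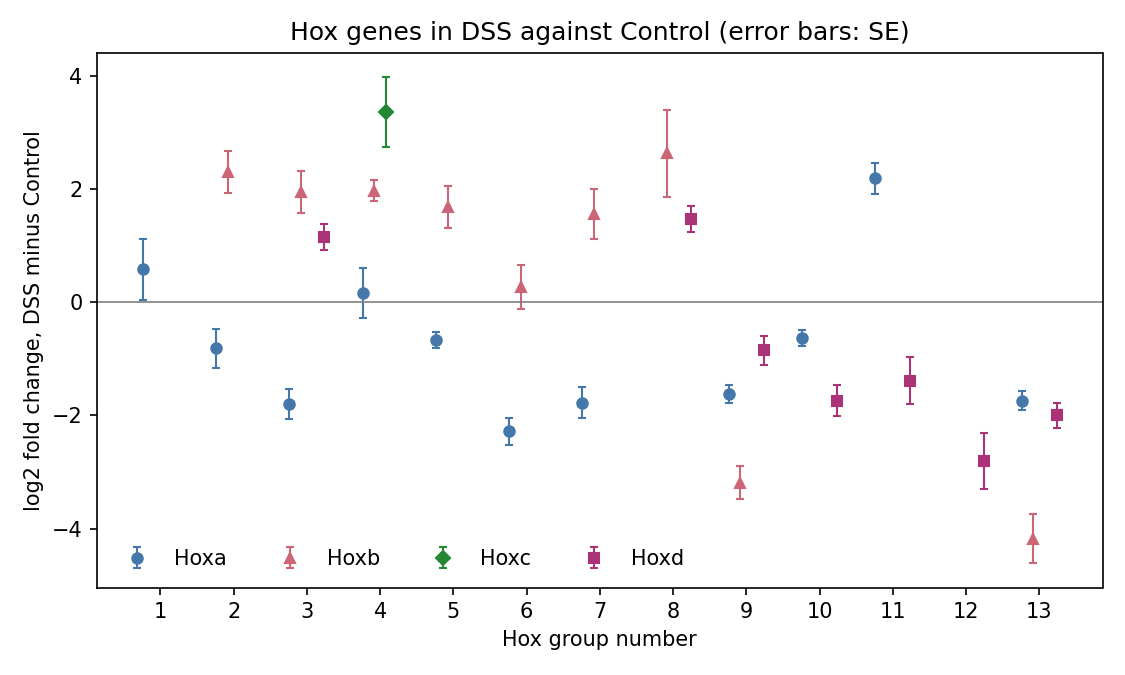
Log2 difference between DSS and Control (vertical axis, points with SE bars) of each tested Hox gene by its group number (horizontal axis), with a symbol and colour for each cluster. Groups 9 to 13 lie below 0 except Hoxa11, with a median of -1.74, and groups 1 to 8 have medians of -0.82 in the A cluster (7 genes), 1.94 in B (7 genes) and 1.31 in D (2 genes), with 1 gene of C at 3.36.

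The lists were compared with all other tested genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 36 lists, which called 23 lists, 11 higher and 12 lower. With an inter-gene correlation estimated from these libraries 0 of the 23 calls held, the smallest camera adjusted p being 0.247. For stem and progenitor markers the estimated correlation was 0.000722, below the preset 0.01, so a higher correlation did not cost this list its call. What else in the estimated setting cost the calls was not tested. The statements on lists rest on the counts of their members and on the preset correlation. Those counts are to be read against the shares over all 14631 tested genes, of which 4740 rose and 4430 fell. All levels come from whole colon tissue, and a change in a transcript's level within cells and a change in the share of the cells that carry it were not separated by this comparison.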

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

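The tests of the epithelial lists other than the one on transcript length, the tests of the Hox genes and the counts of other splits were chosen only after the results were seen. Of the 35 splits of the 8 libraries into groups of 4, 1, the real one, gave as many as 9170 changed genes with edgeR. The highest other gave 0 at the adjusted threshold and 1418 at an unadjusted p under 0.05, against 9693 for the real split. Every other split keeps the difference between DSS and Control inside its groups, which adds to their spread. The 18 splits with 2 libraries of each group on each side gave 11 to 204 genes at an unadjusted p under 0.05, where chance gives 731.6, so they do not show what chance alone gives. For the gene lists 7 of the 35 splits gave at least 23 calls with the preset correlation, the highest other 27. The 6 others are all among the 16 splits that move 1 library of each group and so carry part of the difference between DSS and Control. The 18 splits that move 2 reached at most 15, and whether chance gives as many list calls is left open.

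The 4 epithelial lists (goblet cells, absorptive colonocytes, junctions, and drug and bile acid handling) had 97 tested members with a median log2 difference of -2.04. The enteroendocrine, tuft cell and repair epithelium lists are not among them, were not called and had medians of 1.16, 0.45 and 0.77. A lower share of epithelial cells in the DSS tissue may be part or all of the fall of these 4 lists. A lower share alone would raise markers of the other cell types alike. The smooth muscle score lay 3.27 below the endothelial score (a difference of -3.27, SD 0.535, from -3.91 to -2.67 over the DSS libraries), so these 2 lists did not rise alike. Muscle and vessel genes can change on their own, so this gap cannot decide what lowered the epithelial lists. The median of the 4 epithelial lists was -1.86 with library size only and -2.17 after a trend with transcript length was removed. This argues against the choice between these 2 scalings, or a length trend, as the cause. The length correction moved genes by a median of 0.148, and the Spearman correlation with length across genes, which are not independent, was 0.0630. Loss of epithelial cells, alone or together with changes within them, remains a hypothesis, since cell numbers were not measured.

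Of 11 tested Hox genes of groups 9 to 13, 10 were lower, and of 17 of groups 1 to 8, 9 were higher and 4 lower. Within groups 1 to 8 the A cluster had 0 genes higher and 4 lower, and the B cluster 6 higher and 0 lower. The Hox pattern may come from sampling another segment of the colon. The median of groups 1 to 8 was -0.82 in the A cluster (7 genes) and 1.94 in the B cluster (7 genes), with 1.31 over 2 genes of the D cluster and 3.36 for 1 gene of the C cluster, and sampling of another segment and a response to DSS cannot be told apart here. A lower share of epithelial cells is a candidate explanation for the fall of groups 9 to 13, whose median of -1.74 lies within the range of general epithelial genes (median -2.77, from -3.96 to -1.19). Of these 11 Hox genes 4 lay outside that range, Hoxb13 (-4.18) below it and Hoxd9 (-0.85), Hoxa10 (-0.63) and Hoxa11 (2.18) above it. Whether a lower epithelial share also raises the genes of groups 1 to 8 that were higher was not tested, and the colon segment is not given in the sources used here.

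In 26 of 334 groups of 4 values 1 library lay far from the other 3. For independent normal values chance gives about 1 in 20 groups, or 16.7. The values here are CPM and scores of related genes, some near 0, so 16.7 is a rough guide only. Control replicate 1 held 11 of them, DSS replicate 3 held 4, Control replicate 4 held 3, Control replicate 3, DSS replicate 2 and DSS replicate 4 held 2 each, and Control replicate 2 and DSS replicate 1 held 1 each. In Control replicate 1, Cyp2f2 was at 11.6 CPM (others 26.6 to 29.3), Nox1 at 179.9 (82.2 to 98.0), Il5ra at 0.210 (0), Cd44 at 159 (109 to 117), Nts at 0.560 (0 to 0.0435), Iigp1 at 207 (62.5 to 63.6), Pdia3 at 1943 (1144 to 1278) and Suclg2 at 295 (272 to 275). Its list scores were -0.19 for fatty acid oxidation (others 0.05 to 0.07), -0.51 for smooth muscle (0.14 to 0.19) and 0.28 for endoplasmic reticulum stress (-0.11 to -0.07). Kcne4 was at 7.87 CPM in Control replicate 2 (others 5.74 to 6.10). In Control replicate 3, Ascl2 was at 2.59 (3.05 to 3.09) and Adm at 6.80 (4.52 to 4.78). In Control replicate 4, Krt7 was at 102 (73.9 to 78.7), Sst at 3.22 (2.28 to 2.39) and Hoxb8 at 0.913 (0.0412 to 0.139). Fabp6 was at 0.360 in DSS replicate 1 (others 0 to 0.0580). In DSS replicate 2, Cela1 was at 13.7 (6.17 to 7.22) and Dhcr7 at 19.6 (12.3 to 13.01). In DSS replicate 3, Trpm5 was at 0.278 (1.17 to 1.30), Alas2 at 7.34 (5.05 to 5.19), the T and NK cell score was 1.32 (2.04 to 2.12) and the enteroendocrine score 0.57 (1.10 to 1.14). In DSS replicate 4, Chi3l3 was at 1378 (505 to 557) and Col4a1 at 0.615 (0.339 to 0.377).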

How the results depend on the processing

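Leaving out overlapping genes was chosen after seeing the data. No named gene or list past the threshold in the main fit or an alternative changed direction between them. The direction of other genes was not compared. Most named genes were taken for large changes in the main fit or after their values were seen. Their rates therefore do not carry over to the other tested genes. For named genes 1239 of 1245 values kept their side of the threshold under alternatives other than leaving out a library (6 weaker). When a library was left out 990 of 1000 did so (9 weaker, 1 stronger). For lists 354 of 396 (30 weaker, 12 stronger) and 276 of 288 (7 weaker, 5 stronger) did so. Values past the threshold in neither fit were taken as the same whatever their direction. Of 97 counts and principal component shares 96 were the same. Counts were the same within a ratio of 1.5, and shares by the side of the threshold of their permutation test. The genes changed in DSS against Control numbered 8522 (without Control replicate 3) to 9559 (limma-voom) at the 0.05 threshold and 7274 at 0.01. Named genes that lost the threshold were Pax6, Cidec, Hoxb8 and Col4a1, the last at under 1 CPM in each group. The cause of each change below was not tested, except that the threshold of 0.01 is stricter by construction.

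With DESeq2's size factors the replication-dependent histone genes were at adjusted p = 0.0519 and with overlapping genes left out at 0.0818. With no filter on low counts mast cell and eosinophil markers were at 0.0414, repair epithelium at 0.0414 and small intestine markers at 0.271. At the 0.01 threshold B and plasma cell markers (0.0104), inflammasome genes (0.0139), small intestine markers (0.0229) and histone genes (0.0482) were not past it. With an estimated inter-gene correlation 0 lists passed the list direction tests: adjusted p was 0.247 for stem cells, metalloproteinases and endothelium, 0.378 for colon segment position genes, 0.413 for B and plasma cells, goblet cells, inflammasome and histones, 0.486 for colonocytes and 0.358 for the other 14. The fry rotation test asks whether genes move one way on balance and compares them with no other genes. It called 32 lists and added mast cells and eosinophils (6.42e-04), antimicrobial genes (0.0120), repair epithelium (3.15e-04), enteroendocrine markers (9.40e-04), tuft cells (3.15e-04), hypoxia (0.0238), adipocytes (0.0266), blood and skeletal muscle (2.27e-04) and pancreatic enzymes (3.15e-04).

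With 1 library left out, adjusted p ran from 0.0101 to 0.134 for enteroendocrine markers, 0.0448 to 0.122 for mast cells and eosinophils, 0.0232 to 0.0933 for repair epithelium, 0.0271 to 0.0581 for replication-dependent histone genes and 0.0157 to 0.472 for small intestine markers.

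With the replicate number as a replicate block the genes changed in DSS against Control numbered 9226, 24 lists passed, repair epithelium was at adjusted p = 0.0382 and Cidec at 0.0518. Same-numbered libraries correlated at 0.237, 0.020, 0.111 and -0.116 in their deviations from the group means, not all above 0.1. These values do not show that the numbers pair the animals, and with 4 libraries per group they cannot exclude it. Control replicate 4 correlated best with DSS replicate 3 (0.208), and not every library correlated best with its own number.

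In the simulated data 60% of genes changed 2-fold were recovered at the depth and group size of these libraries, and no other depth was simulated. Only 200 genes were changed there, against 62.7% of tested genes called in the real data, so this recovery does not carry over. The FPKM alternative was not run because no FPKM values were used.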

Other observations

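Gene groups outside the fixed lists were read from the table's own annotation terms, a test chosen after the data were seen. Of 668 terms with 15 to 300 tested genes 53 were higher and 35 lower by camera with the preset correlation, 0 with an estimated correlation (smallest adjusted p 0.374), and other scalings were not run for them. The terms that fell did so beside general epithelial genes with a median of -2.77, 13 of 14 of them lower. Of 25 tested genes of the tricarboxylic acid cycle, which oxidises acetyl-CoA in mitochondria, 23 fell and 2 rose (median -1.13, camera adjusted p = 3.98e-06, and adjusted p = 0.513 with an estimated correlation). Suclg1 and Suclg2, subunits of succinyl-CoA ligase chosen after their values were seen, had log2 differences of -2.36 ± 0.12 and -2.23 ± 0.16. Of 36 tested steroid biosynthesis genes 26 fell and 4 rose (median -1.31, camera adjusted p = 3.44e-04, and adjusted p = 0.513 with an estimated correlation). Among those chosen after their values were seen, Dhcr7, the last enzyme of cholesterol synthesis, had a difference of -2.77 ± 0.17, Hsd3b3 of -4.63 ± 0.37 and Hsd3b2 of -4.17 ± 0.77 (18.0-fold lower, or 29.4-fold without DSS replicate 1), the latter 2 near-identical genes, and Ch25h, which makes 25-hydroxycholesterol, of 4.73 ± 0.35. Of 33 tested genes of tRNA aminoacylation 21 fell and 1 rose (median -0.57, camera adjusted p = 0.00298, and adjusted p = 0.569 with an estimated correlation), among them the mitochondrial synthetase Nars2 (-1.44 ± 0.17), chosen after its values were seen. Of 26 tested genes of mitochondrial translation 16 fell and 0 rose (median -0.48, camera adjusted p = 0.00220, and adjusted p = 0.513 with an estimated correlation).

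Of 18 tested genes of synapse organization 15 rose and 0 fell (median 1.74, camera adjusted p = 0.00221, and adjusted p = 0.513 with an estimated correlation), among them the adhesion proteins Lrrtm2 (4.24 ± 0.49) and Lrrc4 (3.23 ± 0.50), chosen after their values were seen. Enteric neuron and glia markers moved with them, 20 of 22 higher with a median of 2.50. Of 71 tested genes of potassium ion transport 42 rose and 12 fell (median 1.52, camera adjusted p = 0.00498, and adjusted p = 0.513 with an estimated correlation). The channel subunits Kcne4 (4.91 ± 0.29) and Kcnj8 (4.81 ± 0.29) rose and Kcne3 (-5.03 ± 0.22), a subunit found in intestinal epithelium, fell, all chosen after their values were seen.

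Some genes, chosen after their values were seen, had levels unlike those of related genes, and the cause was not tested. Csf1r, the receptor of macrophage growth factor, was at 0.0484 ± 0.0600 to 1.11 ± 0.742 CPM, with a Control mean of 0.0233 CPM without Control replicate 3. Col4a1 was at 0.0825 ± 0.123 to 0.423 ± 0.129 CPM, with a Control mean of 0.0231 CPM without Control replicate 4, and Col4a2, which forms a trimer with it, at 213 ± 48.6 to 1490.0 ± 551 CPM. Ly6g was at 146 ± 30.7 to 203 ± 96.3 CPM and Ngp, another neutrophil gene, at 1.85 ± 0.845 to 261 ± 201 CPM, with a DSS mean of 162 CPM without DSS replicate 4. For genes with a count of 1 to 3 in a group, Fcer1a had a ratio of 39.8 between DSS and Control (95% counting interval 13.3 to 195), and Itln1 was 115-fold lower in DSS (20.1 to 4574), or at least 31.1-fold without DSS replicate 1, the only DSS library with counts.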
